A study of Mus musculus with 12 samples.

How the data were processed

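The libraries came from primary renal tubular epithelial cells that were prepared from the kidney cortex of C57BL/6 mice, per the labels' protocols. Total RNA was taken up in Trizol and treated with DNase, poly(A) RNA was selected on magnetic beads, and stranded libraries were made with a directional kit and sequenced from both ends, per the labels' protocols. The series' design text counts 3 mice of each genotype, so the libraries of a group were treated as separate animals. The 12 libraries fall into 4 groups of 3 by their genotype labels: floxed Setd2 without Cre (wild type below), floxed Setd2 with the Ksp1.3/cre driver (Setd2 knockout), a floxed MYC construct with that driver (MYC), and both floxed alleles with that driver (MYC Setd2 knockout). The floxed Setd2 allele is part of the labels of every group other than MYC.

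The deposited table holds whole-number read counts per gene, not normalized, for 44792 gene symbols, with the chromosome, start and end of each gene as the authors gave them. The submitters' processing notes name cutadapt 1.9.1, Trimmomatic 0.35, FastQC, HISAT2, StringTie and MACS2 2.1.1, and the builds GRCm38 and mm10, without saying what each was used for. The program that made the counts, its strand setting, its treatment of reads that match several genes and the annotation release are not given in the sources used here. Of the symbols, 32097 were matched to the RefSeq annotation of GRCm38.p6. Of the matched symbols, 91.2% started within 1000 bases of the RefSeq start, and 51.3% had both ends in common. Coordinates are printed as the deposited table gives them. In 1 gene symbol the name had been damaged into a number, and 13557 gene symbols had no count in any library. No table column of per-sample values was left unused.

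Total counts per library ranged from 8889185 to 44227191. No pair of libraries was close enough to be 1 library deposited more than once: over genes with at least 50 counts the smallest median chi-square of a pair within a group was 1.85, where sampling noise alone gives 0.45.

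The libraries were looked over for technical groups before any comparison. Mitochondrial ribosomal RNA counts separated them into 3 sets, with over 10000 CPM (read counts scaled to a common library total) in set 1, under 100 CPM in set 3 and values between in set 2. Set 1 held wild type 1, 2 and 3 and Setd2 knockout 1 and 2. Set 2 held MYC 1 and MYC Setd2 knockout 1 and 2. Set 3 held Setd2 knockout 3, MYC 2 and 3 and MYC Setd2 knockout 3. The sets are called counting sets here. They also differed in genes whose reads can be shared: 274 genes had under 1 CPM in all of set 1 and at least 10 CPM in all of set 3, and 91.2% of these overlapped another gene of the table, against 34.9% of the 7060 genes that every library held at 10 CPM or more. The opposite pattern was held by 20 genes. A fit with a term for the 3 sets was therefore added after the data had been seen, and its values stand beside those of the fit by group. No set holds both wild type and MYC libraries. The step from set 2 to set 3 rests on the MYC and MYC Setd2 knockout groups, which have libraries in both. The step from set 1 to the other sets rests on the Setd2 knockout group alone, through its 1 library in set 3, Setd2 knockout 3. So does every value with the set term for MYC against wild type and for MYC Setd2 knockout against Setd2 knockout. Setd2 knockout 3 is also the only library of its group with Xist and without Y-chromosome transcripts, so that step carries a difference between the sexes too. In MYC against wild type the set term moved the median of sex chromosome genes from -0.31 to 11.76. It moved that of kidney genes that differ between the sexes from -1.29 to 1.27.

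Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with library sizes scaled by trimmed means of M values (TMM), the filterByExpr filter, which left 17019 genes, and the quasi-likelihood F test. All 12 libraries entered 1 fit with a coefficient per group, which left 8 residual degrees of freedom (6 with the set term). TMM factors ranged from 0.79 to 1.497. The biological coefficient of variation was 0.58, and 0.27 with the set term. P-values were adjusted by Benjamini-Hochberg over all genes tested, and genes with an adjusted p under 0.05 are called. The comparisons were Setd2 knockout against wild type, MYC against wild type, MYC Setd2 knockout against MYC, MYC Setd2 knockout against Setd2 knockout, and the difference between the first and the third of these (the interaction). Expression per library is given as CPM, or as log2 CPM with a prior count of 2 and TMM scaling.

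Before the data were examined, 42 lists of genes were fixed, which cover growth, the cell cycle, signalling, metabolism, stress and markers of nephron segments and of other cells that a cortex preparation can hold. Of their members, 1383 were matched and 1249 tested, and 3 symbols were not found. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 42 lists, and again with an estimated correlation and with fry. Within each list, p-values were also adjusted over the list alone. The rule for named genes was fixed at the same time. It takes Setd2 and Myc, the 8 called genes with the largest change in each direction, among those with a mean of at least 1 log2 CPM, groups that do not overlap and a plain gene symbol, up to 4 members of each list with the smallest p, 12 marker genes, and the 6 smallest p-values per direction for the interaction. The text names a part of the genes that the rule takes, and some are not reported here.

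The alternatives that were planned are DESeq2 1.42.0, limma-voom, median-ratio factors, total counts without TMM, no filter, a filter of 1 CPM in 3 libraries, a minimum fold change, fits of only the groups compared, the replicate number as a block, a covariate for Y-chromosome transcripts, and leaving out each library in turn. Those added after the data had been seen are the set term, the set term with the Y covariate, the data without the 4 libraries of set 3, genes that overlap no other gene, these with the set term, and set 1 alone for Setd2 knockout against wild type.

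The fits were tested on simulated counts with 200 genes changed by known folds. At 8-fold, the fit by group recovered 52.3% of the changed genes of Setd2 knockout against wild type, 57.8% of MYC against wild type, 48.4% of MYC Setd2 knockout against MYC, 47% of MYC Setd2 knockout against Setd2 knockout and 16.9% of the interaction. At 2-fold it recovered 1.5%, 0%, 0%, 1.5% and 0% in the same order. In the simulated MYC against wild type comparison, 8 of 10 raised lists were recovered and 1 other list was called. Genes were drawn independently there, so this does not give the rate of false list calls in the real data. The estimated correlation reached 0.811 for cytosolic ribosomal proteins in MYC against wild type. Other splits of those real libraries called 12 to 24 lists. Tables were handled and plots drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Splice forms and chromatin marks were not analysed here.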

Results

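Gene expression was measured by RNA sequencing in 12 libraries of primary renal tubular epithelial cells, 3 from each of 4 groups of mice. Setd2 encodes the histone methyltransferase that places trimethylation on lysine 36 of histone H3, and MYC is a transcription factor that drives growth and division. Cre was expressed from the Ksp-cadherin promoter, which is active in tubular epithelium. Wild type mice carried floxed Setd2 without Cre. The Setd2 knockout, MYC and MYC Setd2 knockout mice carried Cre with floxed Setd2, a floxed MYC construct, or both. Total counts ranged from 22997852 to 44227191 in wild type, 16657538 to 41608501 in Setd2 knockout, 15712963 to 17132375 in MYC and 8889185 to 14314434 in MYC Setd2 knockout.

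The libraries did not differ by genotype alone. Mitochondrial ribosomal RNA stood at 15016 to 19622 CPM in the 3 wild type libraries and Setd2 knockout 1 and 2 (set 1), at 975 to 2909 CPM in MYC 1 and MYC Setd2 knockout 1 and 2 (set 2), and at 0.5 to 1.3 CPM in Setd2 knockout 3, MYC 2 and 3 and MYC Setd2 knockout 3 (set 3). Of 78 genes of cytosolic ribosomal proteins, 28 to 31 were under 5 CPM in the libraries of set 1, 10 to 15 in set 2 and 2 to 5 in set 3. Setd2 knockout 3 and MYC Setd2 knockout 1 and 3 held Xist and no Y-chromosome transcripts, and the other 9 libraries held Y-chromosome transcripts. The first principal component carried 63.8% of the variance and the second 12.1%.

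**Figure D1:**
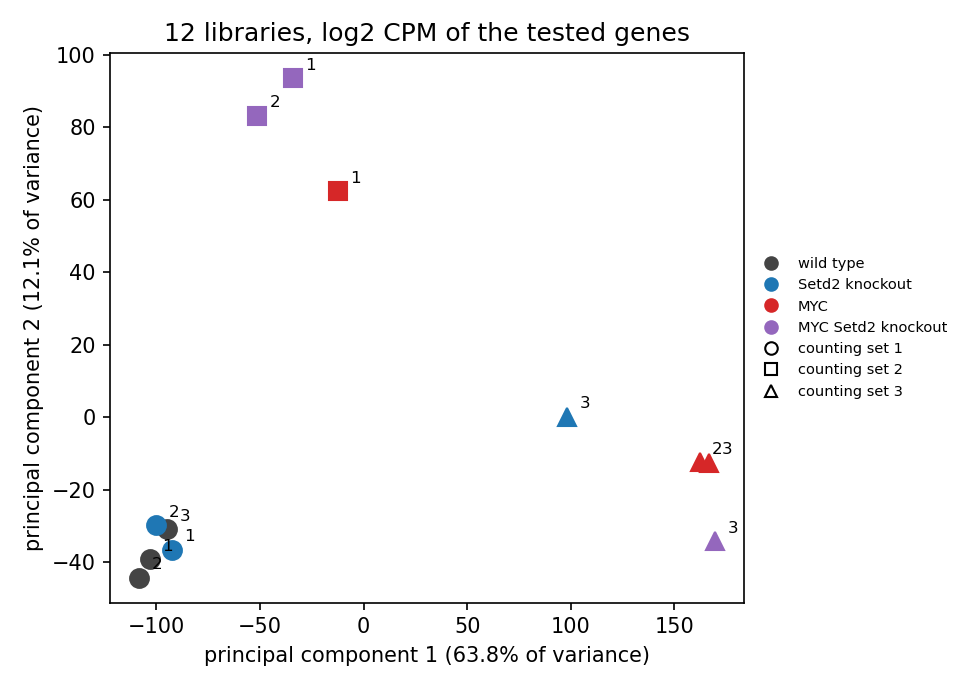
Principal components of log2 CPM of the 12 libraries, with the first component (63.8% of variance) on the x axis and the second (12.1%) on the y axis. Colour gives the group and the marker gives the counting set.

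Setd2, the targeted gene (chromosome 9, 110532597 to 110618633 in the GRCm38 coordinates of the deposited table), was read first in every library. It stood at 55.98, 63.53 and 68.6 CPM in wild type, 50.89, 65.35 and 69.7 CPM in Setd2 knockout, 68.7, 89.73 and 84.99 CPM in MYC, and 57.65, 45.56 and 102.48 CPM in MYC Setd2 knockout. Its log2 fold change was -0.24 ± 0.19 (SE, n = 3 per group) in Setd2 knockout against wild type and 0.10 ± 0.19 in MYC Setd2 knockout against MYC, and neither passed the test (edgeR adjusted p = 1 and 0.900). The counts cover the whole gene, and which exons are floxed is not given in the sources used here, so a deleted exon may leave this value nearly as it was, and the genotypes rest on the labels. Mouse Myc (chromosome 15, 61985341 to 61990361) ranged from 2.26 to 4.38 CPM in wild type and Setd2 knockout, stood at 3.56, 7.06 and 6.05 CPM in MYC, and at 6.03, 2.02 and 17.81 CPM in MYC Setd2 knockout. Its log2 fold change was 0.32 ± 0.52 in MYC against wild type and 1.26 ± 0.53 in MYC Setd2 knockout against Setd2 knockout (edgeR adjusted p = 0.669 and 0.511). Whether transcripts of the MYC construct are counted on this gene is not given in the sources used here.

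**Figure D2:**
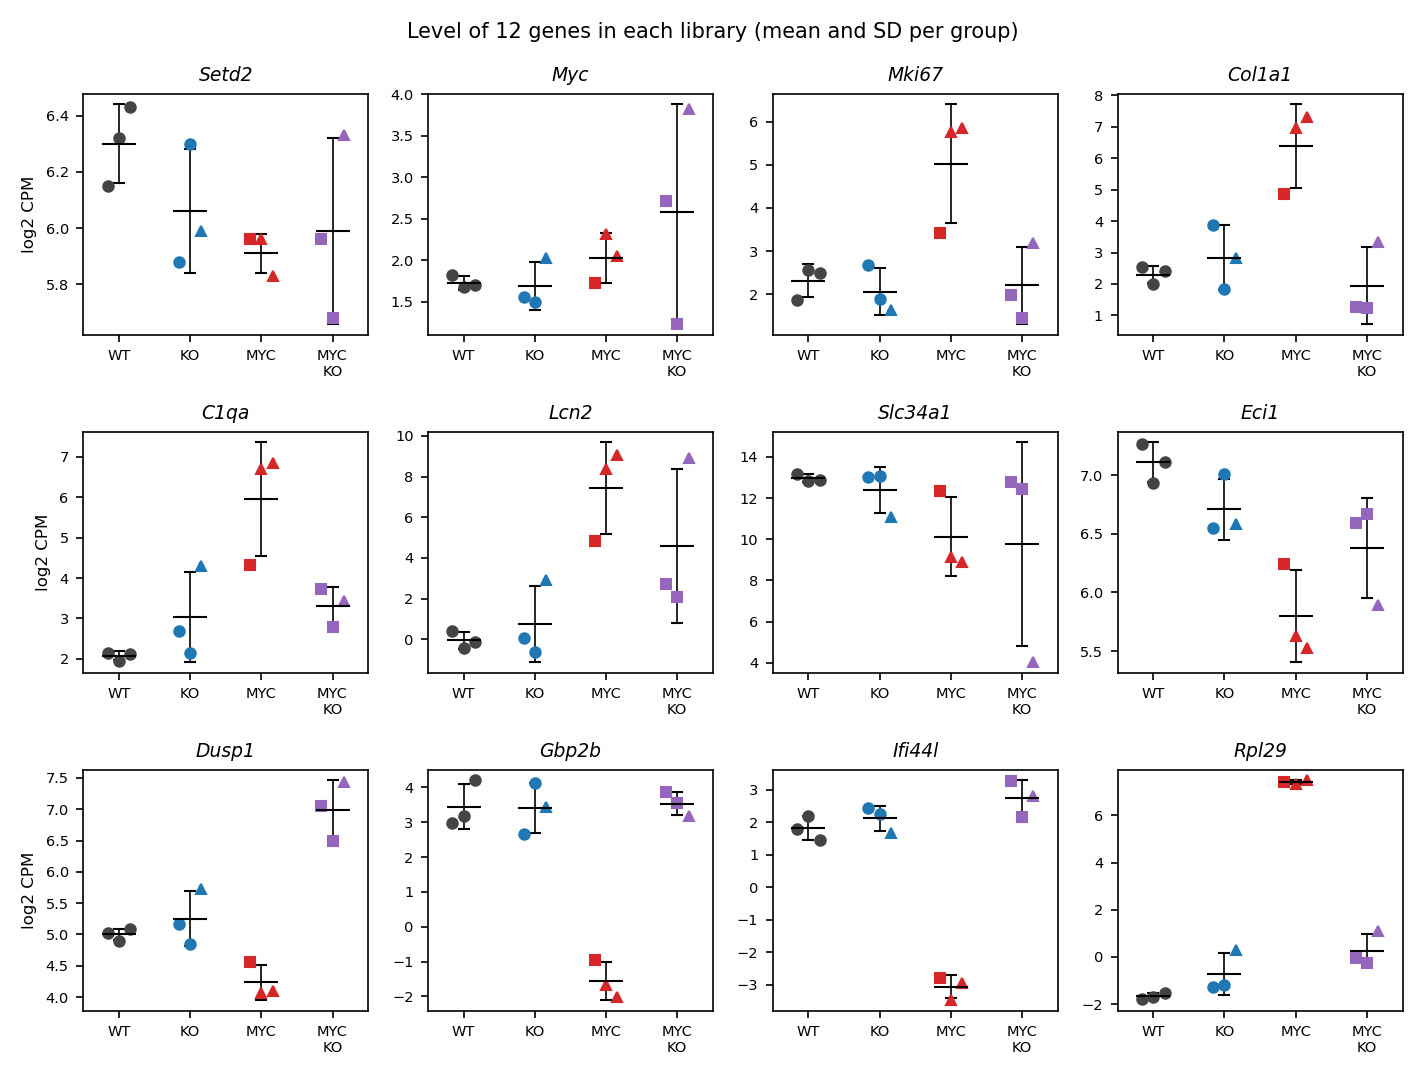
Log2 CPM of 12 genes in each of the 12 libraries, by group, with the mean and SD of each group (n = 3). Setd2 stands between 45.56 and 102.48 CPM in every library, and Rpl29 is high in the 3 MYC libraries.

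Setd2 knockout was compared with wild type to ask what loss of Setd2 changes in tubular cells without the MYC construct. Several lists of genes from cells other than tubular epithelium were higher as a group. Markers of fibroblasts and mural cells had a median log2 fold change of 0.63 (18 of 19 members above 0), with Notch3, a receptor of mural cells, at 0.85 ± 0.34 and Acta2, smooth muscle actin, at 0.62 ± 0.27. Extracellular matrix genes had a median of 0.36, mesenchymal genes 0.37, endothelial markers 0.31 and tubular injury genes 0.41 (camera adjusted p = 2.3e-04, 6.0e-04, 9.9e-04, 0.001 and 0.002 in this order of lists). None of these calls held with an estimated correlation (adjusted p from 0.873 to 0.909 with an estimated correlation). Macrophage markers had a median of 0.99 and cytosolic ribosomal proteins 1.08, but within set 1 their medians were 0.22 and -0.07. Mitochondrially encoded mRNAs had a median of -0.60, which was -0.32 within set 1 (camera adjusted p = 9.4e-04). With an estimated correlation the adjusted p was 0.873 for each of these 3 lists.

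In the test of single genes by edgeR's quasi-likelihood method with Benjamini-Hochberg adjustment, 0 genes rose and 0 fell. At an unadjusted p under 0.05 there were 495 of 17019 genes, a smaller share than the 0.05 that chance alone gives. By limma-voom 0 genes were called, with 42 at an unadjusted p under 0.05, and DESeq2 called 57 higher and 2 lower. With the set term 0 genes were called, with 100 at an unadjusted p under 0.05. Adjusted over the list alone, 0 members of any list rose or fell. Fos and Fosb, transcription factors of the immediate early response, stood at -1.97 ± 0.94 and -3.30 ± 1.30 (edgeR adjusted p = 1 for both). Lists called numbered 14, of which 10 were up and 4 down, and 0 held with an estimated correlation (lowest adjusted p = 0.873 with an estimated correlation). Without Setd2 knockout 1 the lists called numbered 9. Within set 1, which leaves Setd2 knockout 1 and 2 against wild type, the medians were 0.43 for fibroblasts and mural cells and 0.24 for extracellular matrix. They were 0.32 for mesenchymal, 0.36 for endothelial and 0.23 for tubular injury genes. The median log2 CPM of matrix genes was 4.26 and 2.79 in Setd2 knockout 1 and 2, and 3.62, 3.21 and 3.6 in wild type. It was 4.18 and 3.72 against 3.46, 3.67 and 3.94 for injury, and 3.05 and 2.67 against 2.4, 2.17 and 2.85 for mesenchymal genes. For endothelial markers it was 4.94 and 4.99 against 4.27, 4.25 and 5.17. For fibroblasts and mural cells it was 4.17 and 3.91 against 3.63, 3.39 and 3.87. The remaining lists called were the thick ascending limb (0.35), NF-kB and chemokines (0.41) and glycolysis (0.43), and, with negative medians, the proximal tubule (-0.26), DNA damage repair (-0.14, and 0.09 under total counts) and kidney genes that differ between the sexes (-1.19). Within set 1 their medians were -0.09, 0.16, 0.11, -0.02, -0.11 and -0.53 in the same order. Without the libraries of set 3 the thick ascending limb (adjusted p = 0.348), glycolysis (adjusted p = 0.133), proximal tubule (adjusted p = 0.629) and ribosomal protein lists (adjusted p = 0.066) no longer passed camera.

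MYC was compared with wild type to ask what MYC overexpression changes in these cells. By their labels these groups also differ in Cre, which wild type lacks, and in floxed Setd2, which MYC lacks. Genes of cell division were higher as lists. Of 58 tested genes of mitosis and the G2/M phase, 29 rose and 1 fell (51 and 2 adjusted over the list alone), with a median log2 fold change of 2.55. Mki67, a marker of dividing cells, rose by 3.04 ± 0.67 on the log2 scale (SE, n = 3 per group, edgeR adjusted p = 0.042) and Racgap1, which acts in cytokinesis, by 3.55 ± 0.57 (edgeR adjusted p = 0.041). Of 46 genes of DNA replication, 10 rose and 0 fell (18 and 0 adjusted over the list alone), with a median of 0.91, and Uhrf1, which keeps DNA methylation through replication, rose by 3.34 ± 0.60. Both lists passed camera (adjusted p = 1.9e-18 and 8.5e-07), and neither with an estimated correlation (adjusted p = 0.539 with an estimated correlation for both). With the set term the medians were 3.18 and 1.14, but 12 mitosis genes and 1 DNA replication gene rose, and Mki67 stood at 4.09. Without the 4 libraries of set 3, which leaves MYC 1 alone against wild type, mitosis passed camera (adjusted p = 0.003) and DNA replication did not (adjusted p = 0.229).

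Markers of immune cells, matrix and injury were higher in the same comparison. Of 26 macrophage and myeloid markers 19 rose (24 adjusted over the list alone), with a median of 3.59, and the complement genes C1qa, C1qb and C1qc, which macrophages express, rose by 4.27 ± 0.74, 4.05 ± 0.71 and 4.07 ± 0.70 on the log2 scale. Of 20 lymphocyte markers 9 rose (13 adjusted over the list alone), with a median of 2.78, and Cd79a, a part of the B cell receptor, rose by 4.78 ± 1.01. Of 37 extracellular matrix genes 10 rose (22 rose and 1 fell adjusted over the list alone), among them the collagen genes Col1a1, by 4.41 ± 0.84, and Col3a1, by 3.78 ± 0.70, and 8 of 37 mesenchymal genes rose (21 adjusted over the list alone), among them Fn1, fibronectin, by 2.60 ± 0.52. Of 31 tubular injury genes 8 rose (18 adjusted over the list alone), among them Lcn2, an iron carrier that damaged tubules secrete, by 8.35 ± 2.19 (edgeR adjusted p = 0.048), while Havcr1, which codes for the injury marker KIM-1, stood at 6.45 ± 1.84 without passing (edgeR adjusted p = 0.055). Of 27 NF-kB and chemokine genes 9 rose (21 adjusted over the list alone), with a median of 2.08. These lists passed camera (adjusted p from 8.8e-16 for macrophages to 1.8e-05 for lymphocytes), and none with an estimated correlation (adjusted p = 0.539 with an estimated correlation for each). Their medians with the set term were 2.36 for macrophages, 2.95 for lymphocytes, 1.14 for matrix, 1.16 for mesenchymal, 2.07 for injury and 1.67 for NF-kB and chemokine genes. The members that rose with the set term numbered 2, 3, 4, 5, 7 and 2 in the same order. Within the MYC group, the libraries of set 3 exceeded MYC 1 by a median of 2.68 for macrophages, 2.14 for lymphocytes, 1.01 for matrix, 1.61 for mesenchymal, 1.52 for injury and 2.29 for NF-kB and chemokine genes, and by 1.69 for mitosis genes. The mesenchymal (adjusted p = 0.468) and NF-kB lists (adjusted p = 0.129) no longer passed camera without the libraries of set 3.

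The lists of the proximal tubule, of podocytes and of oxidative metabolism were lower, while the thick ascending limb (median 0.63) and principal cells (0.08) did not pass camera (adjusted p = 0.197 and 0.421). Both turned with the set term, to -0.83 and -1.04, and passed as lower (adjusted p = 0.003 and 0.024), as did the distal convoluted tubule at -1.49 (adjusted p = 6.7e-08). With an estimated correlation and the set term the adjusted p of these 3 lists was 0.339, 0.514 and 0.077. The thick ascending limb and principal cell lists passed as higher without the libraries of set 3 (adjusted p = 0.012 for both), and with the set and Y terms neither passed (adjusted p = 0.273 and 0.906), so that their direction depends on the fit. Fatty acid oxidation and peroxisome genes had a median of -0.82 (-0.11 under total counts), with 3 of 49 genes lower (3 adjusted over the list alone). Among them was Eci1, a mitochondrial isomerase of unsaturated fatty acid oxidation, which fell by 1.28 ± 0.27 on the log2 scale (edgeR adjusted p = 0.041). Mitochondrially encoded mRNAs had a median of -1.56, with 1 of 13 lower, and nuclear genes of oxidative phosphorylation -0.64, with 2 of 68 lower (a median of 0.08 under total counts). Proximal tubule genes had a median of -1.53, and 0 of 50 were called by edgeR in the fit by group or adjusted over the list alone, and 12 were lower with the set term, which gave a median of -1.77. Slc34a1, the phosphate carrier of this segment, stood at -1.95 ± 1.51 (edgeR adjusted p = 0.358). Podocyte markers had a median of -2.39, with 1 of 14 lower (8 adjusted over the list alone). With the set term 10 fatty acid oxidation genes were lower, and 0 mitochondrially encoded, oxidative phosphorylation or podocyte genes. Camera's adjusted p was 4.1e-07, 3.8e-07, 1.1e-05, 7.5e-07 and 1.2e-04 for these lists in order, and with an estimated correlation the adjusted p was 0.539, 0.539, 0.743, 0.620 and 0.539. Without the libraries of set 3 the fatty acid oxidation (adjusted p = 0.672) and oxidative phosphorylation lists (adjusted p = 0.599) no longer passed.

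Among growth genes, 34 of 78 cytosolic ribosomal proteins rose in the fit by group (70 adjusted over the list alone), with a median of 2.58, but 1 rose with the set term, with a median of 0.85, and within the Setd2 knockout group alone these genes stood 2.09 higher in the library of set 3 than in those of set 1. Many of them have processed pseudogenes that can share their reads, and their values are uncertain. Among the largest of these changes were those of Rpl29 (chromosome 9, 106429432 to 106431573), at 9.53 ± 0.64 (edgeR adjusted p = 4.6e-04), Rpl11, at 6.84 ± 1.80, Rpsa, at 6.31 ± 1.54, and Rps27rt, at 6.11 ± 1.60, which stood at -0.07 with the set term. Ribosome biogenesis genes, a class that MYC is known to induce, had a median of 0.26 that did not pass camera (adjusted p = 0.094), and 0.73 with the set term (adjusted p = 1.2e-09). That call was lost with an estimated correlation (adjusted p = 0.432 with the set term and an estimated correlation), and the list did not pass without the libraries of set 3 (adjusted p = 0.270). Phgdh, the first enzyme of serine synthesis, rose by 2.64 ± 0.34 on the log2 scale (edgeR adjusted p = 0.033) and Krt18, a keratin of simple epithelia, by 3.33 ± 0.80, while Cdh1, E-cadherin, stood at 0.24 ± 0.37 and Vim, vimentin, at 0.53 ± 0.59, neither called. Among called genes with a mean of at least 1 log2 CPM that the rule for named genes takes, and leaving out loci with only a LOC number, the largest falls were those of TrnP, a mitochondrial transfer RNA, at -7.08 ± 1.26, Gbp2b, an interferon-inducible GTPase (chromosome 3, 142594847 to 142619179), at -5.45 ± 0.59 (edgeR adjusted p = 0.013), ND6, which the mitochondrial genome encodes, at -4.51 ± 0.60, and Malat1, a nuclear non-coding RNA, at -3.87 ± 0.86. H3f3c had 1 count over the 3 wild type libraries and 1485 over the 3 MYC libraries, a ratio of 2970 between their shares of total counts, with an exact 95% interval of 532 to 117000 that covers counting error only. It stood at -1.47 with the set term, and as a copy of other histone H3 genes its count is uncertain. Over the alternative fits the weakest values were -2.72 for TrnP, -2.23 for ND6 and -0.77 for Malat1. Each of these 3 was called in 1 of the 6 fits that leave out a library. TrnP and ND6 are mitochondrial, as is the RNA that defines the sets, so their falls cannot be told apart from set differences.

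By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 957 genes rose and 402 fell in MYC, which is 70.4% rises. Total counts without TMM gave 4810 rises and 232 falls, 95.4% rises, and moved the median gene by 0.75 on the log2 scale, so that all values here are relative to the median gene. The 2 groups did not overlap for 50.6% of genes, where chance gives 10%. With the set term 157 rose and 250 fell (7 and 19 with the set and Y terms), 113 of the 1359 genes called by group were called in both, and 1305 of them had the same sign. The counts rested on single libraries: 1 gene rose and 2 fell without wild type 1, without wild type 2 or without wild type 3, 1 rose and 1 fell without MYC 2, 1 rose and 0 fell without MYC 3, and 2641 rose and 1784 fell without MYC 1. Rpl29 was called in each of these 6 fits. Lists called numbered 18, of which 13 were up and 5 down, and fry called 8. Those not yet given were the fibroblast and mural cell list (median 0.85), intercalated cells (0.82), glycolysis (1.12) and epithelial junctions and keratins (0.63). With the set term these medians were 0.78, 0.00, 0.00 and 0.20 in the same order. Their adjusted p was 0.539, 0.542, 0.539 and 0.743 with an estimated correlation, and from 0.071 to 0.697 with the set term. Without the libraries of set 3 the fibroblast and mural cell list no longer passed (adjusted p = 0.325).

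**Figure D3:**
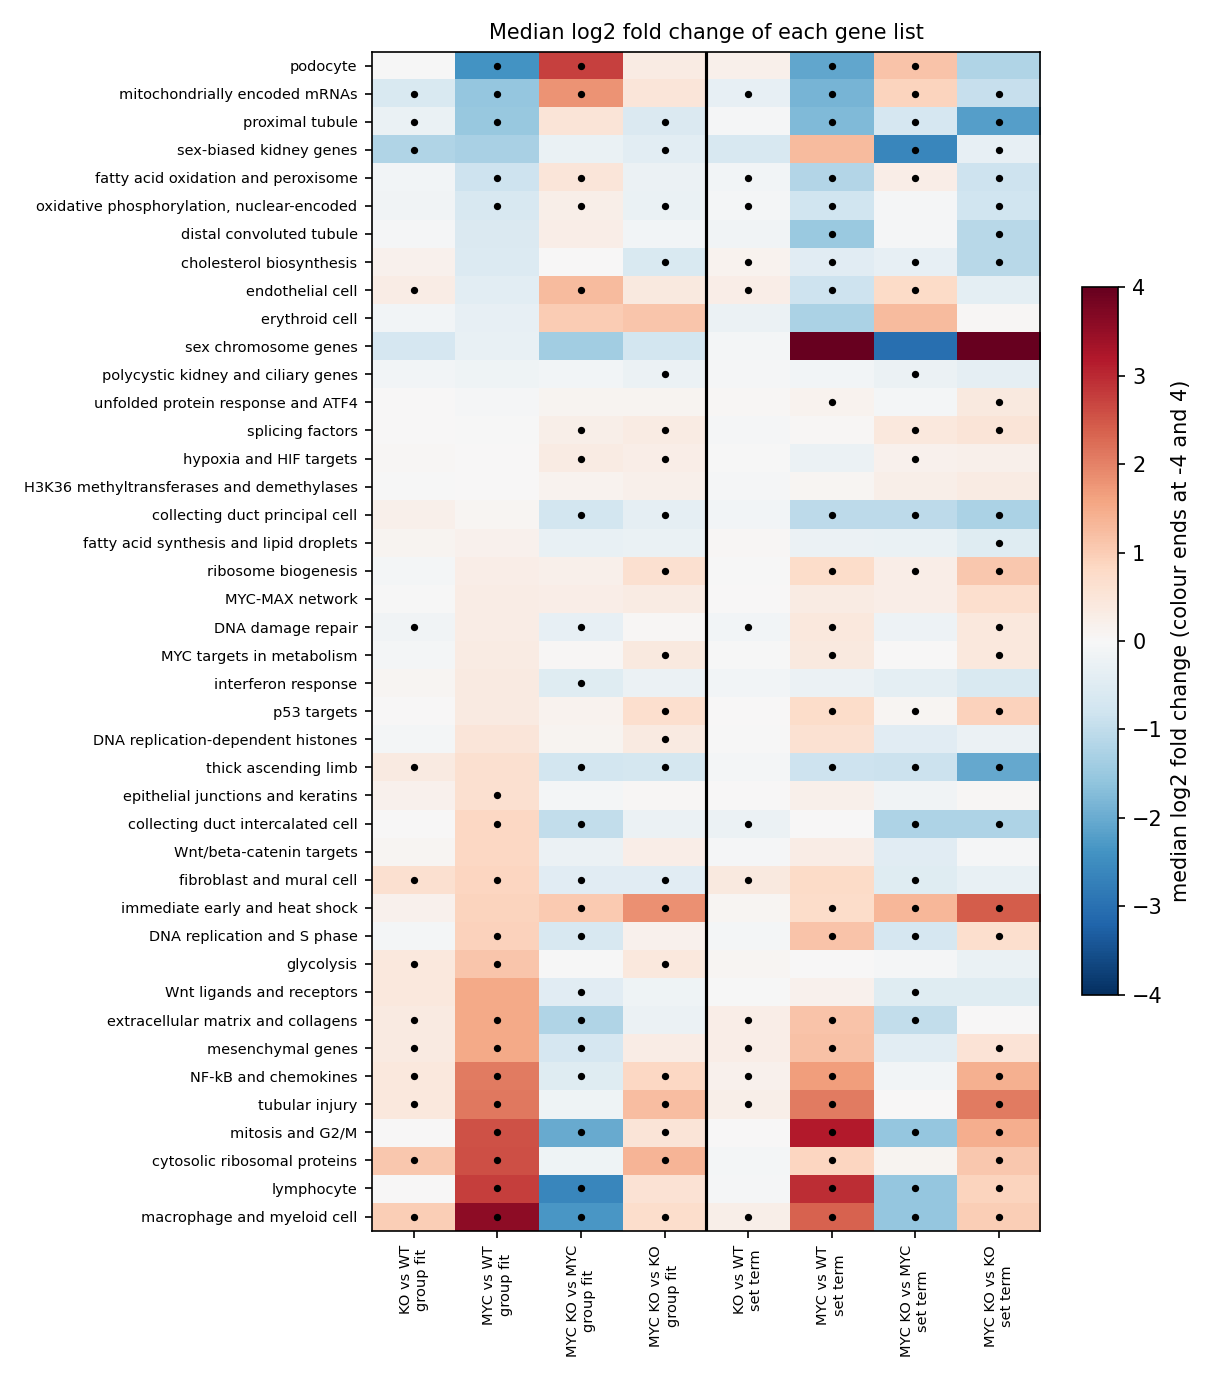
Median log2 fold change of the 42 gene lists in the 4 pairwise comparisons, by the fit by group and by the fit with a term for the counting sets, as colour, with dots where camera called the list. Mitosis genes have medians of 2.55 in MYC against wild type and -2.02 in MYC Setd2 knockout against MYC.

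MYC Setd2 knockout was compared with MYC to ask what loss of Setd2 changes where MYC is overexpressed. Mitosis genes were lower, with a median log2 fold change of -2.02. This comparison and the last share the 3 MYC libraries, and so their chance values. In the fit by group 0 of 58 rose and 0 fell (1 rose and 43 fell adjusted over the list alone), and 9 fell with the set term. Mki67 stood at -2.97 ± 0.67 (edgeR adjusted p = 0.128) and fell by 2.20 on the log2 scale with the set term (edgeR adjusted p = 0.012). E2f2, a transcription factor of the S phase, fell by 2.53 ± 0.37 (SE, n = 3 per group, edgeR adjusted p = 0.037), and DNA replication genes had a median of -0.63. Extracellular matrix genes had a median of -1.20 (0 called, 12 lower adjusted over the list alone), and Col1a1 stood at -4.39 ± 0.85 (edgeR adjusted p = 0.095) and fell with the set term by 3.74 (edgeR adjusted p = 0.007). Markers of intercalated cells had a median of -0.99 (0 called of 16, 5 lower adjusted over the list alone), principal cells -0.72 and the thick ascending limb -0.75. Within set 2 and within set 3 the medians were -0.90 and -2.00 for mitosis, -0.26 and -1.10 for DNA replication, -0.80 and -1.19 for matrix, -1.44 and -1.24 for intercalated cells, -0.66 and -1.18 for principal cells and -1.02 and -1.17 for the thick ascending limb. Camera's adjusted p was 1.6e-28 for mitosis, 6.6e-11 for DNA replication, 2.9e-12 for matrix, 4.6e-09 for intercalated cells, 0.001 for principal cells and 9.7e-04 for the thick ascending limb, and with an estimated correlation the adjusted p was 0.287 for the first 4 of these lists, 0.354 and 0.356.

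Genes of the immediate early response were higher, with 2 of 28 called (7 adjusted over the list alone, 12 with the set term) and a median of 1.06, which was 0.71 within set 2 and 1.78 within set 3 (camera adjusted p = 1.0e-08, adjusted p = 0.287 with an estimated correlation). Dusp1, a phosphatase that ends MAP kinase signals, rose by 2.79 ± 0.30 on the log2 scale (edgeR adjusted p = 0.009), and Klf2, an early transcription factor, by 1.9 ± 0.28 (edgeR adjusted p = 0.037). Markers of other cells moved with them and differed between the sets: macrophage markers had a median of -2.32, which was 0.02 within set 2 and -2.35 within set 3, lymphocyte markers -2.62, which was -0.13 and -2.80, podocyte markers 2.73, which was 2.84 and -0.50, endothelial markers 1.28, which was 1.23 and 0.07, and mitochondrially encoded mRNAs 1.80, which was 1.94 and -0.24. With an estimated correlation the adjusted p of these lists was 0.338, 0.287, 0.301, 0.300 and 0.287. The hypoxia list, with Adm called at 2.06 ± 0.33, had a median of 0.33 (-0.01 under total counts). Splicing factors had 0.22 (-0.12 under total counts) and fatty acid oxidation 0.47 (0.10 under total counts). Wnt ligands and receptors had -0.46, with Wnt9b, a ligand of kidney development, at -3.77 ± 0.55 (edgeR adjusted p = 0.037). With an estimated correlation the adjusted p of these 4 lists was 0.287, 0.711, 0.356 and 0.287. Mesenchymal genes (-0.67), NF-kB and chemokines (-0.48), DNA damage repair (-0.32) and fibroblasts and mural cells (-0.45) were also called as lower by camera. Oxidative phosphorylation was called as higher (0.24, and -0.17 under total counts). Within set 2 these medians were 0.30, 0.22, -0.10, -0.82 and 0.11, and within set 3 -0.83, -0.49, -0.30, -0.83 and -0.17. With an estimated correlation their adjusted p was 0.543, 0.650, 0.356, 0.287 and 0.821. Without the libraries of set 3 the DNA replication, macrophage, lymphocyte, hypoxia and fatty acid oxidation lists no longer passed camera. The same held for the mesenchymal, NF-kB, DNA damage repair and oxidative phosphorylation lists.

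By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9 genes rose and 21 fell, and with the set term 482 rose and 456 fell, including all 30. Besides those named, and among called genes with a mean of at least 1 log2 CPM that the rule takes, the largest rises were those of Gbp2b, at 5.45 ± 0.59 (edgeR adjusted p = 0.009), and Cyp26b1, which degrades retinoic acid, at 5.38 ± 0.70, followed by Acpp, an acid phosphatase, at 2.18 ± 0.35, and Cyp2d22, at 1.77 ± 0.27. Within the same limit, the largest falls were those of Rpl29, at -7.06 ± 0.57 (edgeR adjusted p = 0.003), the oxysterol hydroxylase gene Cyp7b1, at -5.30 ± 0.77, Bcat1, an enzyme of branched-chain amino acids, at -4.83 ± 0.66, Tnn, at -3.37 ± 0.50, Ptger1, at -3.32 ± 0.49, whose span overlaps another gene, Esr1, the estrogen receptor, at -3.09 ± 0.38, and Pdlim3, at -2.84 ± 0.40. The deposited table places Bcat1 on a scaffold and not on a chromosome, and whether this affects its count was not tested. Ifi44l, an interferon-induced gene (chromosome 3, 151758737 to 151762891), had 2 counts over the 3 MYC libraries and 246 over the 3 MYC Setd2 knockout libraries. That is a ratio of 186 between their shares of total counts, with an exact 95% interval of 50.9 to 1540 for counting error. Against the 262 counts of wild type the ratio was 65.6 (18 to 544). The interferon response list moved the other way in the fit by group, with a median of -0.48 and 10 of 39 members above 0. Camera's adjusted p for it was 0.044, 0.815 with an estimated correlation and 0.309 with the set term. Its median was 0.59 within set 2, the direction of Ifi44l, and -1.34 within set 3, so its direction differed between the sets. The 3 MYC libraries all held Y-chromosome transcripts and 2 of the 3 MYC Setd2 knockout libraries did not, and with the set and Y terms 9 genes fell and 6 rose. The counts moved with single libraries: 123 rose and 318 fell without MYC 1, 316 rose and 258 fell without MYC Setd2 knockout 3, 1 rose and 2 fell without MYC 2 or without MYC 3, and 3 rose and 2 fell without MYC Setd2 knockout 1 or without MYC Setd2 knockout 2. Rpl29 and Ifi44l were called in each of these 6 fits. The fit of only these groups called 0 genes by edgeR, with 1080 at an unadjusted p under 0.05, while DESeq2 called 318 higher and 479 lower and limma-voom 2 and 4.

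MYC Setd2 knockout was compared with Setd2 knockout to ask what MYC overexpression changes where Setd2 is deleted. Immediate early genes were higher as a list, with a median log2 fold change of 1.83 and 20 of 28 members higher adjusted over the list alone. No list of this comparison held in camera with an estimated correlation (lowest adjusted p = 0.247). Jun, Junb and Atf3, transcription factors of the stress response, stood at 1.9 ± 0.42, 2.64 and 4.82 by group without passing (edgeR adjusted p = 0.503 for each, n = 3 per group). With the set term they rose by 2.79 ± 0.52, 3.39 ± 0.51 and 5.85 ± 1.02 (edgeR adjusted p = 0.016, 0.008 and 0.013). On the Setd2 knockout side, every set-term value of this comparison rests on 1 library, Setd2 knockout 3. Tubular injury genes had a median of 1.23, and with the set term 16 rose and 2 fell, among them Sox9, a factor of tubule repair, by 4.73 ± 0.80, Lcn2 by 5.37 ± 0.93 and Havcr1 by 8.02 ± 1.57. Ribosome biogenesis genes had a median of 0.63, and 20 rose with the set term (42 adjusted over the list alone), among them Npm1, a nucleolar protein, by 1.73. Proximal tubule genes had a median of -0.59, and with the set term 24 of 50 fell (35 adjusted over the list alone), with a median of -2.19. Markers of other cells and ribosomal protein genes differed in the same comparison. Macrophage markers had a median of 0.70, fibroblast and mural cell markers -0.45 and cytosolic ribosomal proteins 1.37 (camera adjusted p = 0.002, 0.004 and 2.1e-31), and with an estimated correlation the adjusted p was 0.750, 0.540 and 0.540. Between the 2 libraries of set 3 these medians differed by -0.01, -0.56 and 1.27.

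Further along the nephron, the thick ascending limb list had a median of -0.71, with 7 genes lower with the set term, and principal cells -0.35, with 6 lower. Slc12a1, the salt carrier of the thick ascending limb, and Aqp4, a water channel of principal cells, fell by 2.40 and by 6.67 ± 0.75 on the log2 scale with the set term (edgeR adjusted p = 0.012 and 0.004). Cholesterol synthesis genes had a median of -0.61, with 8 lower with the set term, among them Cyp51, at -3.52 ± 0.29 (edgeR adjusted p = 0.001). Set 3 alone holds both groups, with 1 library each, Setd2 knockout 3 and MYC Setd2 knockout 3, and there the medians differed by 2.50 for immediate early, 2.12 for injury, 1.41 for ribosome biogenesis, -2.59 for proximal tubule, -1.96 for thick ascending limb and -1.22 for cholesterol genes. Without the libraries of set 3 the ribosome biogenesis (adjusted p = 0.951), thick ascending limb (0.526) and principal cell lists (0.545) did not pass camera. The median of the ribosome biogenesis genes was 4.32, 4.45 and 5.76 log2 CPM in MYC Setd2 knockout 1, 2 and 3, and 4.46, 4.61 and 4.37 in Setd2 knockout 1, 2 and 3. For injury genes it was 3.93, 4.27 and 6.02 against 4.18, 3.72 and 4.12. For proximal tubule genes it was 9.1, 9.3 and 5.18 against 9.45, 9.73 and 8.69. In each of these lists MYC Setd2 knockout 3 stood furthest from the Setd2 knockout libraries. Immediate early genes were higher in every library, at 5.1, 4.26 and 5.82 against 3.32, 3.39 and 3.73. Camera's adjusted p by group was 3.0e-22, 6.1e-08, 5.1e-08, 2.1e-07, 8.7e-04 and 2.9e-06 for these 6 lists, and with an estimated correlation the adjusted p was 0.247, 0.540, 0.628, 0.639, 0.540 and 0.540. In the fit by group 0 genes rose and 0 fell by edgeR, with 1625 at an unadjusted p under 0.05. Limma-voom called 0, with 1616 at an unadjusted p under 0.05, and DESeq2 called 79 higher and 107 lower. The set term gave 528 rises and 978 falls, and 281 rose and 130 fell by group without Setd2 knockout 3, where no counting set holds both groups. Lists called numbered 21, and 9 without Setd2 knockout 3.

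The interaction asks whether the effect of Setd2 loss differs with MYC. Cre and the floxed allele do not cancel in it, since wild type lacks Cre and MYC lacks floxed Setd2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 1 gene had a positive and 1 a negative interaction. Rpl29 stood at -8.40 ± 0.76 (adjusted p = 0.008) and Ifi44l at 7.28 ± 0.82 (adjusted p = 0.031). Neither Setd2, at 0.34 ± 0.27, nor Mki67, at -2.77 ± 0.90, nor Col1a1, at -5.15 ± 1.11, passed (edgeR adjusted p = 0.650, 0.484 and 0.345). Both counts were 0 without wild type 1, without wild type 2, without wild type 3 and without MYC Setd2 knockout 1. Without Setd2 knockout 1, without Setd2 knockout 2 and without MYC 3 there were 0 positive and 1 negative, without MYC 1 there were 2 and 3, and without MYC Setd2 knockout 3 there were 18 and 13. DESeq2 called 47 and 239, the set term 6 and 12, and the set and Y terms 0 and 1. Camera called 24 lists, 8 up and 16 down, among them mitosis with a median of -1.94 and extracellular matrix with -1.61, and 0 held with an estimated correlation (lowest adjusted p = 0.429 with an estimated correlation).

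No gene was called the same way by edgeR in the 2 comparisons for Setd2 loss, since 0 were called in Setd2 knockout against wild type (495 at an unadjusted p under 0.05), or in the 2 comparisons for MYC, since 0 were called in MYC Setd2 knockout against Setd2 knockout (1625 at an unadjusted p under 0.05). DESeq2 gave 3 and 136 such genes. With the set term, 91 genes were higher and 212 lower in both comparisons for MYC, where independent lists would share 4.87 and 14.37. With a term for Y-chromosome transcripts as well, the 303 genes in both fell to 25. The set coefficients are shared by both of those comparisons and the step from set 1 rests on Setd2 knockout 3, so part of this overlap can come from them. Without Setd2 knockout 3 the overlap by group was 399 genes. Both comparisons then set libraries of set 1 against libraries of sets 2 and 3, so this overlap cannot separate MYC from the sets.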

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

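Of the tests below, those of the shares of other cell types, of the ribosomal protein genes within the Setd2 knockout group, of Setd2 counts and of the position of genes found only in the MYC libraries were chosen after the result had been seen, as were the fits with a term for the counting sets and of set 1 alone. The results given here were picked out because the effect of Setd2 loss differed between mice with and without the MYC construct in the interaction test.

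The interaction log2 fold change was -8.40 for Rpl29 and 7.28 for Ifi44l. Both genes stood apart in the MYC libraries, the only group whose labels lack floxed Setd2. Among the gene lists that camera called for the interaction, the median was -1.94 for mitosis and G2/M, -0.60 for DNA replication and S phase, -1.61 for extracellular matrix and collagens, -0.99 for mesenchymal genes, -0.91 for Wnt ligands and receptors, -0.29 for epithelial junctions and keratins and -0.49 for tubular injury. For markers of nephron segments it was 1.01 for the proximal tubule, -1.16 for the thick ascending limb, -0.64 for principal cells and -0.95 for intercalated cells. For other cells it was 2.69 for podocytes, 0.86 for endothelial cells, -1.30 for fibroblasts and mural cells, -2.98 for macrophages and myeloid cells and -2.03 for lymphocytes. It was -0.87 for NF-kB and chemokines, 0.71 for immediate early and heat shock genes and 0.33 for hypoxia and HIF targets (-0.27 under total counts). It was -0.79 for glycolysis, 0.35 for nuclear genes of oxidative phosphorylation (-0.28 under total counts) and 2.37 for mitochondrially encoded mRNAs. It was 0.63 for fatty acid oxidation and peroxisome and -1.20 for cytosolic ribosomal proteins. Every list given here moved down under total counts, to 0.04 for fatty acid oxidation, 0.16 for endothelial cells and 0.20 for immediate early genes among others. The glycolysis, tubular injury and oxidative phosphorylation lists no longer passed camera under total counts. With the set term the median turned to 0.20 for cytosolic ribosomal proteins, to 0.09 for tubular injury and to -0.68 for the proximal tubule, and it moved by over 2 times to 0.97 for podocytes, -1.42 for macrophages, -0.19 for glycolysis, 0.03 for oxidative phosphorylation, 1.16 for mitochondrially encoded mRNAs, 0.30 for fatty acid oxidation, -0.40 for Wnt ligands and receptors and -0.13 for epithelial junctions. The lists of epithelial junctions, tubular injury, endothelial cells, NF-kB, glycolysis and oxidative phosphorylation no longer passed camera with the set term (adjusted p from 0.087 to 0.601). Of the lists called in both fits, 16 kept their direction and 2 were called in the opposite direction with the set term. Without the libraries of set 3 the lists of DNA replication, mesenchymal genes, the proximal tubule, macrophages, lymphocytes, NF-kB, hypoxia, glycolysis, oxidative phosphorylation and fatty acid oxidation no longer passed camera (adjusted p from 0.081 to 0.723). None of these lists held with an estimated correlation (adjusted p from 0.429 to 0.799). Chance could not be excluded for the interaction: 9 of 100 splits of the 12 libraries called as many genes as the real split, which called 2 (highest other 2043), and 15 of 100 called as many lists as the real 24 (highest other 26).

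The first pattern weighed is the 1359 genes called by edgeR in MYC against wild type, none of whose groups share a counting set. Overlapping genes counted differently between the sets of libraries are argued against as the whole cause, since 31.8% of the called genes overlap another gene, against 41.2% of those tested and 91.2% of the genes seen in set 3 and missing in set 1. A lower share of proximal tubule cells with more of every other cell type is argued against too. Podocyte markers had a median of -2.39 (quartiles -2.62 to -1.03) while macrophage markers stood at 3.59 (3.04 to 4.06). Other changes in the mix of cells stay open, since this test covers only a rise of every other type. Podocyte markers also varied within a genotype, with medians of 6.19, 6.04 and 2.81 log2 CPM in MYC Setd2 knockout 1, 2 and 3. For the ribosomal protein genes, a difference in counting may account for most of the change, because Setd2 knockout 3 exceeded Setd2 knockout 1 and 2 by a median of 2.09, against 2.58 for MYC against wild type. More immune cells in the MYC kidneys and an effect of MYC itself stay open. Cre, which wild type lacks, and differences between the counting sets other than gene overlap stay open as well. Strain variants, linked or not to the floxed Setd2 that MYC lacks, were not tested in this comparison. The 10 splits of these 6 libraries are too few to exclude chance (real 1359 genes and 18 lists, highest others 0 and 24). In the fit by group 1 rise and 0 falls were left without MYC 3, and 1 and 1 without MYC 2. There were 1 and 2 without any 1 of the wild type libraries, against 2641 and 1784 without MYC 1.

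The second pattern is that edgeR called 0 genes in Setd2 knockout against wild type, with 495 at an unadjusted p under 0.05, 57 higher and 2 lower by DESeq2 and 0 by limma-voom. Setd2 knockout 3 standing apart from the other libraries of its group is argued against as the only cause. With the 5 libraries of set 1 alone 0 genes were called (167 at an unadjusted p under 0.05). In simulated counts that fit recovered 42.4% of genes changed by 2-fold and 83.6% of those changed by 4-fold, with 23 false calls. Set 1 has its own structure, which that fit leaves out and which may widen its spread. The median chi-square was 2.24 between wild type 3 and Setd2 knockout 2 and 3.24 between wild type 1 and Setd2 knockout 1. Between Setd2 knockout 1 and 2 it was 5.47. Wild type 3 and Setd2 knockout 2 held 0.641% and 0.561% of counts on an 18S ribosomal RNA gene, against 0.031% to 0.039% in the other libraries of set 1. Changes hidden by that spread stay open. Deletion of Setd2 in few of the sampled cells cannot be told apart from an intact deletion with little effect: Setd2 in the Setd2 knockout libraries was 0.812 to 1.11 times the wild type mean, and a count over the whole gene may miss a deleted exon. A small effect of Setd2 loss on RNA levels in these animals stays open and was not tested. The 10 splits are too few to exclude chance (real 0 genes and 14 lists, highest others 0 and 14).

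The third pattern is the difference between MYC and MYC Setd2 knockout, since MYC is the only group whose labels lack the floxed Setd2 allele, so that strain variants carried along with that allele could differ between these groups. Of the 938 genes called with the set term, 3.2% lie within 20 Mb of Setd2, against 1.79% of the other genes tested (odds ratio 1.81, 95% interval 1.19 to 2.66, Fisher's exact test, two-sided p = 0.004), which is consistent with linked variants for some of these 30 genes, though only 6 higher and 9 lower genes are called with the set and Y terms. In 35 genes the 3 MYC libraries stood apart from all others by at least 1.5 log2 units. Only 1 of these genes, Rpl29, lies within 20 Mb of Setd2, at 4.1 Mb. This argues against linked variants as the cause for the other genes with a chromosome position, which Bcat1, on a scaffold, lacks. Unlinked strain variants, counting of reads from pseudogenes and an effect of Setd2 loss stay open, and no test here separates them. The 10 splits are too few to exclude chance, and the split that parts set 2 from set 3 (MYC 1 and MYC Setd2 knockout 1 and 2 against MYC 2 and 3 and MYC Setd2 knockout 3) called 5349 genes against the real 30, which points to a structure of the samples; the fit with the set term called 482 higher and 456 lower, and for lists the real split called 22 and the highest other 25.

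For MYC Setd2 knockout against Setd2 knockout the 10 splits are also too few to exclude chance, with 0 genes by edgeR in the real split (1625 at an unadjusted p under 0.05, 0 by limma-voom, 79 higher and 107 lower by DESeq2) and 26 in the highest other, and with 21 lists against 25 in the highest other.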

How the results depend on the processing

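The alternatives with a term for the counting sets, without the 4 libraries of set 3, with genes that overlap no other gene and with set 1 alone were chosen after the data had been seen, and all others were planned. Counts are given as higher and lower, or as positive and negative for the interaction, and the cause of each change was not tested except where fewer genes or samples explain it. Median-ratio factors, the filter of 1 CPM in 3 libraries and the minimum log2 fold change of 1 left every count of genes within 1.5 times of the value reported. Of genes changed by 2-fold in counts simulated at the depths of these libraries, 1.5% were recovered in Setd2 knockout against wild type and 0% in MYC Setd2 knockout against MYC, and 18.2% and 15.2% with the spread and the fit of the set term, so depth alone did not set the limit in these 2 comparisons. The set term left 1.5% in MYC against wild type, 3.1% in MYC Setd2 knockout against Setd2 knockout and 1.5% for the interaction, against 0%, 1.5% and 0% by group.

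DESeq2 called 57 and 2 in Setd2 knockout against wild type, 3124 and 1646 in MYC against wild type, 318 and 479 in MYC Setd2 knockout against MYC, 79 and 107 in MYC Setd2 knockout against Setd2 knockout, and 47 and 239 for the interaction. It called 3 genes the same way in both comparisons for Setd2 loss and 136 in both for MYC. Limma-voom called 483 and 208 in MYC against wild type, 2 and 4 in MYC Setd2 knockout against MYC, and 0 positive for the interaction. Total counts only gave 4810 and 232 in MYC against wild type, 4 and 11 in MYC Setd2 knockout against MYC, and 0 positive for the interaction. Under total counts the median gene stood at 0.22 in Setd2 knockout against wild type, 0.75 in MYC against wild type, -0.33 in MYC Setd2 knockout against MYC, 0.16 in MYC Setd2 knockout against Setd2 knockout and -0.56 for the interaction, where TMM gave -0.01 to 0.05. With no filter on low counts 234 were lower in MYC against wild type. With only the 2 groups compared, edgeR called 3187 and 1795 in MYC against wild type and 0 and 0 in MYC Setd2 knockout against MYC, where 1080 had an unadjusted p under 0.05 and other tools called those given above.

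With the replicate block, 1466 and 813 were called in MYC against wild type, 11 lower in MYC Setd2 knockout against MYC, and 0 positive for the interaction. Same-numbered libraries had correlations of their deviations from -0.6 to 0.68, over 0.1 in 11 of 18 pairs and in every pair for 1 of 6 pairs of groups, so the numbers were not taken to pair the libraries. With the covariate for Y transcripts, 2676 and 1085 were called in MYC against wild type, 44 lower in MYC Setd2 knockout against MYC and 3 negative for the interaction.

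With the counting-set term, 157 and 250 were called in MYC against wild type, 482 and 456 in MYC Setd2 knockout against MYC, 528 and 978 in MYC Setd2 knockout against Setd2 knockout and 6 and 12 for the interaction, and 303 genes moved the same way in both comparisons for MYC. With the counting-set and Y-transcript terms these were 7 and 19, 9 lower, 615 and 1134, 0 positive, and 25 genes. Leaving out the 4 libraries of set 3 gave 1828 and 1118, 339 and 368, 896 and 442, 69 and 97, and 952 genes, where the MYC and MYC Setd2 knockout groups keep 1 and 2 libraries and the lone MYC library is assumed to vary like the other groups. With genes overlapping no other gene the interaction had 2 and 3, and with the counting-set term as well, 122 and 170, 304 and 352, 389 and 643, 7 and 15, and 221 genes.

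With an estimated correlation 0 lists were called in each of the 5 comparisons, and fry called 0 in Setd2 knockout against wild type, 8 in MYC against wild type and 0 in the other 3, while camera at its preset correlation called 14, 18, 22, 21 and 24.

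Leaving out each library in turn gave 0 to 0 genes higher and lower in Setd2 knockout against wild type by edgeR, where 495 had an unadjusted p under 0.05 with all libraries. It gave 1 to 2641 higher and 0 to 1784 lower in MYC against wild type, with the highest without MYC 1, and 1 to 316 higher and 2 to 318 lower in MYC Setd2 knockout against MYC, with the highest without MYC Setd2 knockout 3 and without MYC 1. It gave 0 to 281 higher and 0 to 130 lower in MYC Setd2 knockout against Setd2 knockout, with the highest without Setd2 knockout 3, and 0 to 18 positive and 0 to 13 negative for the interaction, with the highest without MYC Setd2 knockout 3. Lists called ranged from 9 to 16 in Setd2 knockout against wild type (9 without Setd2 knockout 1), 17 to 20, 20 to 25, and 9 to 23 in MYC Setd2 knockout against Setd2 knockout (9 without Setd2 knockout 3), and from 21 to 25 for the interaction. Genes moving the same way in both comparisons numbered 0 to 0 for Setd2 loss and 0 to 399 for MYC. The 399 came without Setd2 knockout 3, where both comparisons for MYC also part set 1 from the other sets.

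Of 4771 values of named genes under an alternative, 3874 kept their side of the threshold, 583 lost a call and 308 gained one. Values called in neither fit are among the 3874 whether or not they turned direction. In 6 the direction turned where the fit by group or the alternative called the gene. These were Rps27rt in MYC against wild type, at -0.07 with the counting-set term and -0.03 with the Y term as well, H3f3c, at -1.47, at -1.37 with the Y term and at -1.39 with genes overlapping no other gene and the counting-set term, and Vim in MYC Setd2 knockout against MYC, which moved from -0.01 to 1.83 (edgeR adjusted p = 0.018) without the libraries of set 3.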

Other observations

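Of the genes described here, the 35 that stood apart in the MYC libraries were chosen after their values had been seen, as those where each of the 3 MYC libraries lay at least 1.5 log2 units beyond all 9 others. In 31 of them the MYC libraries were higher and in 4 lower. Several are known from stratified or urinary tract epithelium and not from tubules: the basal keratins Krt5 and Krt15, the uroplakins Upk2 and Upk3a, and Ly6d. Krt5 stood at 3.34, 3.68 and 5.62 log2 CPM in MYC 1, 2 and 3 and at -0.22 or below in the other 9 libraries, a gap of 3.56. The gap was 2.60 for Ly6d, 1.80 for Krt15, 1.67 for Upk3a and 1.55 for Upk2. Markers of this epithelium were not among the lists, and no test of their source was run.

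Rpl29 and Gm6344 had the largest gaps, 6.26 and 6.79 log2 units. Rpl29 held 3218, 3689 and 4559 counts in MYC 1, 2 and 3, and from 4 to 37 counts in the other libraries, which lie in all 3 counting sets. Ifi44l and Gbp2b, both on chromosome 3, had the largest gaps in the other direction, 4.25 and 3.62.

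Kidney genes known to differ between the sexes had a median difference of -4.13 between MYC Setd2 knockout and MYC within set 2 and of -4.11 within set 3, where their median log2 fold change in the fit by group was -0.26. Within set 2 the difference came from MYC Setd2 knockout 1, at a median of 2.13 log2 CPM, while MYC Setd2 knockout 2 stood at 8.65 and MYC 1 at 8.28. Of the MYC Setd2 knockout libraries, 1 and 3 held Xist, at 4363 and 33517 counts, and no Y-chromosome transcripts. Xist counts were 16612 in Setd2 knockout 3 and from 1 to 23 in the 9 libraries with Y-chromosome transcripts.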
